A study of Mus musculus with 2 samples.

How the data were processed

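Single-cell RNA was measured in hearts of mouse embryos at embryonic day 10.5, with 4 hearts pooled for each of 2 groups and 1 library per group. Per the labels' protocols, embryos were kept on ice for 3 hours during genotyping, hearts were digested with TrypLE in steps of 5 minutes and strained at 70 µm, and libraries were made with the 10x Chromium 3' v3.1 kit and read at 100 bp. The deposited matrices hold counts of UMIs per gene and barcode, made by the authors with Cell Ranger 7.1.0 on genome build mm10, per the file headers and the submitters' processing notes. They hold every barcode, not only cells, and are not normalised. The cell filters, clustering and tests of the authors are not given in the sources used here. No annotation of cells by the authors was used here.

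Genes were placed on chromosomes with GENCODE vM21, and 50 of the 32285 genes had no match. A barcode was taken as a cell when its UMI total reached 10% of the 99th percentile of the top barcodes (the order-of-magnitude rule), which gave minimums of 2862 UMIs for the library labelled wildtype and 5208 for the library labelled knockout. In turn, 11246 and 5730 barcodes passed. A minimum of 500 genes removed 3714 barcodes labelled wildtype, whose UMIs were 88.6% hemoglobin with a median of 6162 UMIs, and 0 labelled knockout. A limit of 20% mitochondrial UMIs removed 43 and 38. Doublets were scored with the Scrublet method of scanpy, and the highest scores were removed at 0.8% per 1000 cells of the library, which took 449 (6.00%) and 259 (4.55%). The caller's own automatic thresholds would have marked 263 and 308. This left 7040 cells with 72467578 UMIs and 5433 cells with 100805905 UMIs. The labels state no number of cells.

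Cells of both libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours, with the Leiden method at resolution 1, which gave 29 clusters. No batch correction was applied. A cluster was named for a class when at least 3 and at least 50% of the class's fixed markers were at least 2-fold above the mean of the other clusters, after 10 CPM were added to each. At least 1 marker also had to be among the cluster's top 10 genes by fold, with no other class having more there. Other clusters were left unnamed. Sub-clusters of cardiomyocytes with at least 3 markers of another class among their top 10 genes were called mixed and held 45 cells labelled wildtype (7.48%) and 55 labelled knockout (9.23%). Cardiomyocyte subtypes were taken from the highest of 5 marker scores. Clustering proved sensitive to the last digits of the arithmetic, so the numerical libraries were held to 1 thread and a fixed instruction set.

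UMIs were summed per library and class, scaled to CPM and compared as the log2 ratio of the library labelled knockout to the library labelled wildtype. With 1 library per group no test was run, no p-value is given and no count of changed genes was made. Ratios have an exact conditional binomial interval, levels an exact Poisson interval and shares an exact Clopper-Pearson interval, all at 95% and for counting error only. A share of 0 is given with the limit that 3 cells of the total would allow. The median gene of cardiomyocytes was at 0.11 and that of erythroid cells at 2.14, so values of these classes are given relative to it where so stated; in the other 3 compared classes it lay between -0.06 and -0.01.

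In all, 27 gene lists were fixed before the data were examined, together with the markers, the comparisons and most alternatives. They cover the spindle assembly checkpoint and kinetochore without Bub1b, G2/M phase, S phase, p53 targets, pro-apoptotic genes, cyclin-dependent kinase inhibitors, interferon response, sarcomere, calcium handling and ion channels, cardiac transcription factors, trabecular myocardium, compact myocardium, glycolysis, hypoxia response, nuclear genes of oxidative phosphorylation, the mitochondrial genome, unfolded protein and integrated stress response, heat shock, immediate early genes of dissociation, Notch and endocardial-to-mesenchymal transition, extracellular matrix, Bmp targets, Wnt targets, Fgf and Erk targets, neuregulin and Igf signalling, hemoglobin, and the sex of the embryos (X inactivation and Y chromosome). Some genes stand in several lists, among them 9 genes of the spindle and G2/M lists and Cdkn1a, Bax and Gja5. Genes with at least 20 UMIs over both libraries in the class were used. A list's median was placed among 10000 random lists of the same size matched over 20 bins of expression, and "rose" or "fell" is said only of lists outside the 2.5th to 97.5th percentile. The percentile describes these 2 libraries and is no test. Each member was counted as higher, lower or holding 0 by its counting interval.

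Single genes were named by a rule, among genes with at least 200 UMIs in the class and 50 CPM in the higher library. Mitochondrial, ribosomal, hemoglobin and Y-linked genes, Xist, Tsix and unnamed gene models were left out, while other genes of the X chromosome were kept. The rule took the 12 highest and 12 lowest ratios in cardiomyocytes and the 5 highest and 5 lowest in each other class. Bub1b was added in every class, and up to 4 members of each list outside its range and up to 3 of the others. Bub1, Bub3, Mad2l1, Ttk, Mki67 and Top2a were set beside Bub1b for comparison. Genes that change with developmental stage, such as Lin28b and Igf2bp1, were added outside this rule after values had been seen.

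To compare cells of unequal depth, each was thinned to 4630 UMIs, the 10th percentile of the shallower library, and shallower cells were left out. Cycling cells were those with at least 3 UMIs of the G2/M or the S list. Chromosome imbalance was measured as the variance between cells of each autosome's share of UMIs over its binomial variance, with order-statistic intervals over 19 autosomes. The dose of a chromosome in a cell was its share at 5000 UMIs relative to the median cell of the same class and library, scaled to the cell's own median chromosome. Hemoglobin, cell cycle and variable genes were left out, and the 5000 UMIs count only the genes kept for the dose. It was called gained at 1.3 or more and lost at 0.7 or less, with 10000 simulated equal cells as the reference. This measure was added after the variance ratio was seen. Free RNA was profiled from barcodes under 100 UMIs, and its upper limit in a class came from the hemoglobin UMIs of that class.

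The steps were tested on simulated data drawn from the summed profile of the cells richest in Tnnt2 in the library labelled wildtype, at the depth of each library. Of the intervals over 13645 genes, 95.7% held the true ratio, and genes set higher or lower by log2 0.5 (50 each) had an interval on the true side of 0 in 96% and 94%. Of unchanged lists 95.2% lay inside the range, and a G2/M list set lower by 0.3 came back at -0.29. With 18272 genes, 99% of chromosomes set to 1.5 times were called, 99.8% of those set to 0.5 times, and 0.167% of equal cells had a call. Alternatives covered the minimum of UMIs and of genes, the mitochondrial limit, doublet removal, cluster resolution, naming by score, scaling, thinning, free RNA, gene minimums and subsets of cardiomyocytes. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.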

Results

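Single-cell RNA libraries were made from mouse hearts at stage E10.5, with 4 hearts pooled per library and 1 library per genotype. One pool was BubR1+/+ and the other BubR1fl/fl, and both carried 1 copy of Nkx2.5-cre. This Cre recombines floxed alleles in cardiac progenitors and the cells that come from them, cardiomyocytes among them. Of the classes compared for Bub1b, only erythroid cells and macrophages were taken beforehand as unmarked by it. BubR1, the product of Bub1b, belongs to the spindle assembly checkpoint, which delays the separation of chromosomes until all are attached to the spindle. The question was what loss of this checkpoint protein does to the cells of the embryonic heart. The file labelled wildtype held 122834180 UMIs over 1451246 barcodes, and the file labelled knockout held 130039314 UMIs over 1632950 barcodes. After filtering, 7040 cells labelled wildtype were kept, with medians of 9290.5 UMIs and 2851 genes, against 5433 cells labelled knockout, with medians of 17116 UMIs and 4291 genes. With 1 library per genotype there was no replicate check and no test. Square brackets give 95% intervals that cover counting error only, and levels are in CPM, the common scaling of a gene's UMIs to the UMI total of its cell class. Ratios are log2 ratios of the library labelled knockout to the library labelled wildtype.

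Bub1b (ENSMUSG00000040084, mm10 chromosome 2, 118598211 to 118641591) was lower in cardiomyocytes of the library labelled knockout and higher in most other classes. In cardiomyocytes it stood at 57.1 CPM [52.3, 62.2] in the library labelled wildtype (522 UMIs) and at 31.1 CPM [28.1, 34.4] in the library labelled knockout (379 UMIs), a log2 ratio of -0.88 [-1.07, -0.68]. The median gene of cardiomyocytes had a log2 ratio of 0.11, and relative to it Bub1b stood at -0.99. Of the genes set beside it, Bub1, its partner at kinetochores, had a plain log2 ratio of -0.12 [-0.30, 0.07], Bub3 of 0.29, Mad2l1 of 0.07 and Ttk of 0.08, while Mki67 at -0.64 [-0.75, -0.54] and Top2a at -0.26 [-0.33, -0.19] were lower too. Macrophages also had less Bub1b, at 87.5 against 49.0 CPM (-0.84 [-1.30, -0.40], 212 and 54 UMIs), with Bub1 at 0.02.

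The library labelled knockout held more Bub1b in 4 classes and over all cells. The log2 ratio of Bub1b was 0.50 [0.27, 0.73] in endothelial/endocardial cells (24.3 to 34.4 CPM), 0.37 [0.07, 0.67] in cushion/outflow mesenchymal cells (40.5 to 52.2 CPM) and 0.88 (lower bound 0.67) in epicardial cells (24.1 to 44.5 CPM). In erythroid cells it was 2.87 [2.54, 3.20] (4.49 to 32.7 CPM), or 0.72 relative to a median gene at 2.14, and over all kept cells 0.37 [0.30, 0.44]. Bub1 stood above Bub1b in each of the 4 classes. It was at 0.67 in endothelial/endocardial, 0.72 in mesenchymal, 1.37 [1.15, 1.59] in epicardial and 4.99 [4.30, 5.78] in erythroid cells. Intervals of both genes lay apart in epicardial and erythroid cells. In endothelial/endocardial cells Bub3 (0.41) and Mki67 (0.09) stood below Bub1b. The deleted part of Bub1b is not given in the sources used here, and a 3' read that lies outside it checks nothing, so these values are no proof of either label. A Bub1b UMI was found in 35.5% of cardiomyocytes labelled wildtype [31.7, 39.5] and 32.4% labelled knockout [28.6, 36.3], at median depths of 13604.5 and 18399 UMIs. After every cell was thinned to 4630 UMIs, which left out 42 shallower cells labelled wildtype and 0 labelled knockout, the shares were 14.5% [11.7, 17.7] and 10.6% [8.22, 13.3]. In erythroid cells the shares were 4.45% and 42.7% before thinning, at median depths of 11262.5 and 20444 UMIs, and 2.08% and 13.9% after it. The free RNA of the droplets would bring at most 47.4 of the 379 Bub1b UMIs in cardiomyocytes labelled knockout.

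**Figure D1:**
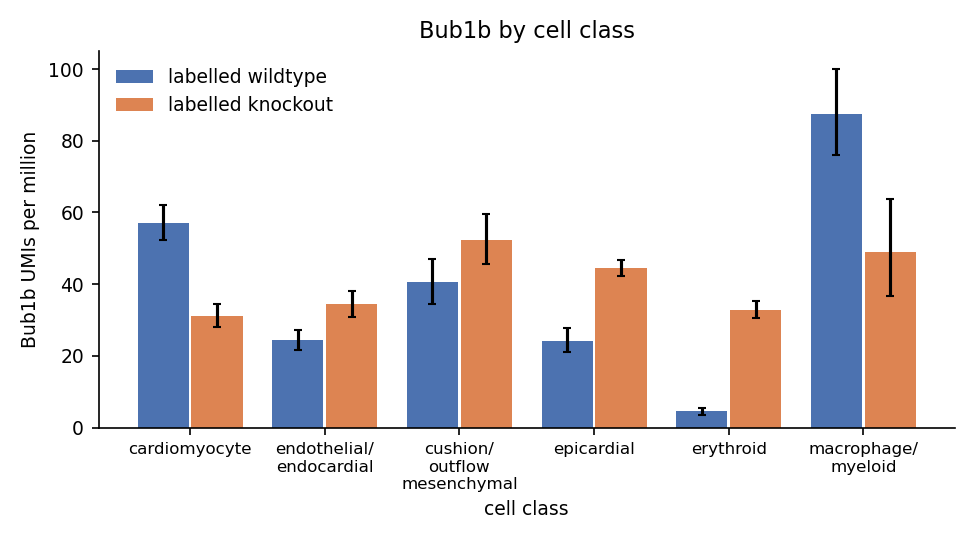
Bub1b CPM of each cell class, in bars for the library labelled wildtype and the library labelled knockout, with 95% Poisson intervals for counting error. Cardiomyocytes fell from 57.1 to 31.1 and macrophages from 87.5 to 49.0, while the other 4 classes were higher in the library labelled knockout.

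The main heart cell types were found in both libraries, but mostly in different clusters. Cardiomyocytes made up 11.9% of non-blood cells labelled wildtype [11.0, 12.8] and 14.1% labelled knockout [13.0, 15.2], with exact Clopper-Pearson intervals here and for all shares. Most came from cluster 13 in the library labelled wildtype (419 of 602 cells) and from cluster 19 in the library labelled knockout (436 of 596 cells). Endothelial/endocardial cells made up 27.9% [26.6, 29.1] and 18.0% [16.9, 19.2], led by cluster 11 and by cluster 2, and mesenchymal cells, all of cluster 4, 9.49% [8.70, 10.3] and 7.74% [6.96, 8.59]. Epicardial cells made up 18.2% [17.2, 19.3] and 48.1% [46.6, 49.7], from cluster 6 in one library and clusters 25 and 24 in the other. Erythroid cells made up 23.9% of all kept cells labelled wildtype and 19.5% labelled knockout; without the minimum of genes, an alternative chosen after the data were seen, they were 4089 of 10193 and 1059 of 5433 cells. Clusters left without a name held 32.3% of non-blood cells labelled wildtype [31.0, 33.6] and 10.3% labelled knockout [9.40, 11.2]. A class held by separate clusters can be set by genes that differ between the libraries, and the minimum of UMIs per cell was 2862 in one library and 5208 in the other, so the shares carry no direction. Hepatic (54) and epithelial (19) cells came only from the library labelled knockout, and 0 of 7040 cells labelled wildtype allows a share of up to 0.0426%; smooth muscle cells (13) came only from the library labelled wildtype, with a limit of 0.0552% in the other.

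Within cardiomyocytes, the mitotic genes were lower and the p53 targets higher in the library labelled knockout. Changes in this class are given relative to its median gene, clusters 13 and 12 holding most cells labelled wildtype and clusters 19 and 12 most cells labelled knockout. The G2/M list fell, with a median of -0.29 at percentile 0 of random lists matched on expression (-0.18 [-0.26, -0.03] before the median gene was taken off): 26 of its 53 genes were lower, 5 higher and 22 had an interval that holds 0. Examples are Mki67 at -0.76 (171 to 109 CPM), the spindle protein Hmmr at -0.80, the cytokinesis protein Anln at -0.72 and Gas2l3 at -0.86. The spindle checkpoint and kinetochore list without Bub1b also fell, at -0.23 (percentile 0.41; 9 lower, 3 higher, 12 holding 0 of 24), with Nuf2 at -0.60, Knl1 at -0.58, Cenpe at -0.50 and Kntc1 at -0.48. The S phase list stayed inside the range of random lists at -0.03 (percentile 46.0; 14 higher, 3 lower, 25 holding 0), and its sign turns from 0.08 before the median gene was taken off. The p53 targets rose, at 0.19 (plain 0.30 [0.13, 0.53], percentile 98.9, 13 higher, 4 lower, 8 holding 0 of 25). They were led by Eda2r at 3.26 (5 and 69 UMIs) and by the cell cycle inhibitor Cdkn1a at 1.32 (17.8 to 47.9 CPM, plain log2 ratio 1.43 [1.17, 1.69]). Pro-apoptotic genes stayed inside, at -0.10 (percentile 18.8; 5 higher, 1 lower, 11 holding 0), with Bax at 0.19. Cyclin-dependent kinase inhibitors fell as a list, at -0.49 (percentile 0.14; 4 lower, 2 higher of 8), with Cdkn2c at -2.39 and Cdkn1b at -0.97 against the rise of Cdkn1a. On the plain scale the interval of their median [-2.28, 1.68] holds 0, as does that of the spindle list [-0.20, 0.13]. In atrial cells alone, relative to their own median gene, the G2/M list stood at 0.18 and the spindle list at 0.095. When all cells were thinned, the spindle list went from -0.11 to 0.047 on the plain log2 scale.

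The share of cycling cells was not informative. At least 3 UMIs of the G2/M list were found in 94.8% [92.6, 96.5] of thinned cardiomyocytes labelled wildtype and 96.6% [94.9, 97.9] labelled knockout, so nearly every cell passed. At a minimum of 20 UMIs, chosen after these shares were seen, they were 43.4% [39.2, 47.6] and 47.1% [43.1, 51.2], within counting error of each other. For the S phase list the shares were 76.1% and 79.4% at 3 UMIs and 11.6% [9.07, 14.6] and 7.55% [5.56, 9.97] at 20 UMIs, so their direction changed with the minimum. Unthinned, the G2/M shares at 3 UMIs were 99.2% and 99.8%, and thinned erythroid cells gave G2/M shares of 24.8% and 99.4%. Free RNA differs between the libraries and stays open as a source, so no cycling is read from these shares.

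Contractile, energy and oxygen genes were lower in cardiomyocytes labelled knockout. The sarcomere list fell, at -0.40 (plain -0.29 [-0.48, 0.01], percentile 0; 16 lower, 6 higher, 3 holding 0 of 25), with the troponin Tnnt2 at -0.93, the myosins Myh7 at -0.88 and Myl2 at -0.79 and Mybpc3 at -0.78. Nuclear genes of oxidative phosphorylation fell, at -0.43 (percentile 0; 22 lower, 3 higher of 26), with Sdhb at -0.71, Ndufs1 at -0.66 and Atp5b at -0.56. Glycolysis (-0.33, percentile 0.26; 10 lower, 2 higher of 16) and hypoxia genes (-0.34, percentile 0.1; 10 lower, 4 higher of 18) fell, with Aldoc at -1.31, Pfkm at -0.72, Ndrg1 at -1.66 and Bnip3 at -0.87. Calcium handling genes (-0.32, percentile 0.14; 10 lower, 8 higher of 19) and trabecular genes (-0.34, percentile 0.47; 6 lower, 5 higher of 12) fell too, with Sln at -2.30, Gja5 at -1.51 and the atrial peptide Nppa at -1.97. Within ventricular cells alone, relative to their own median gene, the trabecular list turned to 0.74 and calcium handling genes stayed inside the range (percentile 40.8). The sarcomere list stood at -0.22 there (percentile 0.53, 15 lower, 9 higher), with a plain-scale interval [-0.48, 0.29] that holds 0. Myl2 and Myh7 are among the markers that score cells as ventricular. In atrial cells alone, relative to their own median gene, glycolysis stood at 0.34, hypoxia at 0.25 and oxidative phosphorylation at 0.058.

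Bmp, Notch, Wnt, Fgf and matrix lists were higher in cardiomyocytes labelled knockout as a class. The Notch and Fgf lists did not rise in every subset of these cells, nor the matrix list under every alternative. Bmp targets rose, at 1.57 (percentile 100; 9 higher, 1 lower of 10), with Msx2 at 2.59 and the Bmp-induced regulators Id1 at 2.77, Id3 at 2.66 and Id4 at 1.92. The Notch and endocardial-to-mesenchymal transition list rose, at 1.15 (percentile 100; 13 higher, 1 lower, 4 holding 0 of 18), with Sox9 at 3.63, Twist1 at 2.84 and Bmp4 at 2.27. Wnt targets (0.75, percentile 99.8; 5 higher, 0 lower of 7) and Fgf and Erk targets (0.59, percentile 99.7; 5 higher, 1 lower of 10) rose, with Lef1 at 3.91, Nkd1 at 1.51, Etv5 at 1.64 and Dusp6 at 1.41. Extracellular matrix genes rose, at 1.21 before the median gene was taken off (percentile 100; 16 higher, 5 lower of 25), with Has2 at 4.14 (3 and 76 UMIs), Hapln1 at 3.93 and Fbln2 at 2.45. Plain-scale intervals of the Wnt [-0.03, 4.02], Fgf and Erk [-0.39, 1.53] and matrix medians [-0.07, 1.75] hold 0. Within ventricular cells alone, the plain Notch and transition median was 0.33 (percentile 96.45) and the matrix median 0.14 (percentile 82.2). Both lay inside the range of random lists. So did the Fgf and Erk list in atrial cells alone, at 0.19 (percentile 88.5). On the plain scale the matrix list turned to -0.03 after free RNA was subtracted, to -0.12 in atrial cells and to -0.16 at a mitochondrial limit of 10%, and Fbln2 turned to -0.36 without sub-clusters that carry markers of another class.

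The remaining lists lay inside the range of random lists in cardiomyocytes. Cardiac transcription factors stood at 0.09 (percentile 89.4; 10 higher, 6 lower), with Gata4 at 0.09 and Tbx20 at -0.20, compact myocardium at -0.08 (percentile 31.6; 4 higher, 3 lower), with the cyclin Ccnd2 at 0.92, and neuregulin and Igf signalling at 0.10 (percentile 85.2; 7 higher, 4 lower), with Erbb4 at 0.32 and Igf2 at -0.75. Unfolded protein genes stood at 0.09 (percentile 82.4; 7 higher, 3 lower), with the chaperone Hspa5 at 0.49, heat shock genes at 0.05 (percentile 71.0; 8 higher, 2 lower), with Hspa8 at 0.43, and immediate early genes, which dissociation can induce, at -0.24 (percentile 5.23; 4 higher, 3 lower). The interferon list stood at -0.14 (percentile 19.2; 2 higher, 1 lower of 8) and the mitochondrial genome at -0.16 (percentile 12.5; 2 higher, 7 lower of 13). Hemoglobin genes, for which free RNA and admixed erythroid cells were not told apart, were outside the range at -3.15 (percentile 0).

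**Figure D2:**
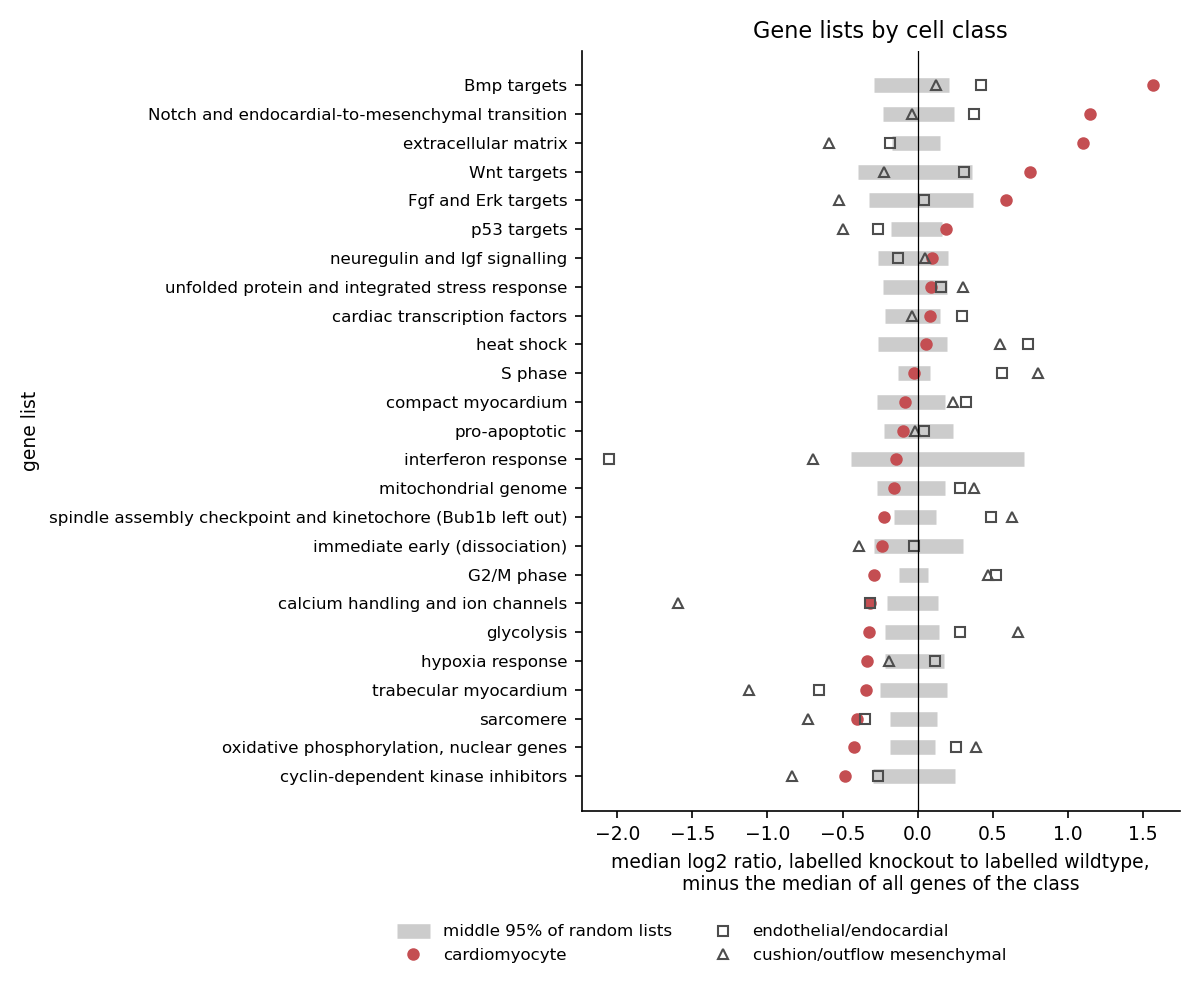
Median log2 ratio of each fixed gene list, labelled knockout to labelled wildtype, less the median of all genes of the class, for cardiomyocytes (filled circles), endothelial/endocardial cells (squares) and mesenchymal cells (triangles). Grey bars are the middle 95% of 10000 random lists in cardiomyocytes. The G2/M list sits at -0.29 in cardiomyocytes and above 0 in both other classes, and the p53 targets at 0.19 and below 0 in both; in atrial cells alone, less their own median gene, the G2/M list was at 0.18.

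Of single genes in cardiomyocytes, the 12 with the highest ratios included Lef1, a Wnt-responsive transcription factor (5.03 to 81.7 CPM), the keratin Krt8 at 3.28, the netrin receptor Unc5c at 2.89, Hmga2, a chromatin protein of embryonic cells, at 2.79 (22.7 to 170 CPM), the cadherin Cdh11 at 2.78 and the Wnt enhancer Rspo3 at 2.49. The other 6 were Id1, Frmd4b at 2.72, Id3, the Bmp-binding protein Bmper at 2.65, tenascin Tnc at 2.62 and Cadm1 at 2.57. The 12 lowest included muscle creatine kinase Ckm at -6.17 (203 to 3.04 CPM), myoglobin Mb at -4.35 (603 to 31.9 CPM), the troponin Tnnt1 at -3.03 and the calcium store protein Casq2 at -2.78. Also among them were Fgf12 at -4.08, Lrrc4c at -3.96, Spint2 at -3.85, Sept6 at -3.84, Mlf1 at -3.29, Sema5a at -2.73 and Snap91 at -2.46. Ckm, Mb, Tnnt1, Fgf12 and Nppa are also among the 10 genes that most set apart cluster 13 or cluster 12.

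The mix of cardiomyocytes differed between the libraries. By highest marker score, 68.6% of cardiomyocytes labelled wildtype [64.7, 72.3] and 40.9% labelled knockout [37.0, 45.0] were ventricular, and 19.9% [16.8, 23.4] and 8.89% [6.73, 11.5] atrial. Outflow tract cells made up 3.82% [2.44, 5.68] and 15.9% [13.1, 19.1], atrioventricular canal cells 4.49% [2.98, 6.46] and 18.8% [15.7, 22.2], and sinoatrial cells 3.16% [1.91, 4.88] and 15.4% [12.6, 18.6]. These are ranges of a score, not types: 8 and 22 ventricular cells lay within 0.1 of the next score, and the canal and outflow markers Rspo3, Msx2, Bmp4 and Tnc were themselves higher in the library labelled knockout. Bub1b went from 65.6 to 33.6 CPM in ventricular, from 36.2 to 26.4 in atrial, from 35.0 to 30.6 in outflow tract and from 27.7 to 26.1 in atrioventricular canal cells, and in sinoatrial cells the other way, from 6.46 (19 cells) to 32.1 CPM (92 cells). The p53 targets stood at 0.37 and the Bmp targets at 1.24 on the plain log2 scale within ventricular cells, and the G2/M list at -0.27.

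The share of UMIs from each autosome varied more from cell to cell in cardiomyocytes labelled knockout. The variance between cells of a chromosome's share of UMIs was 2.84 times the binomial variance in cardiomyocytes labelled wildtype and 4.04 times in those labelled knockout, as medians over 19 autosomes. The median ratio of variances was 1.62, with an interval that lay above 1 and reached 1.82, above 1 for 15 of 19 autosomes, and 2.26 [1.87, 2.70] within ventricular cells. No other class of the 5 had an interval above 1, with ratios of 0.946 (interval from 0.830, holding 1) in endothelial/endocardial, 0.897 [0.794, 0.997] in mesenchymal, 0.917 [0.755, 1.01] in epicardial and 0.647 [0.536, 0.722] in erythroid cells.

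In many cardiomyocytes labelled knockout the share of UMIs from a chromosome lay far from that of the median cell. A chromosome was taken as gained or lost in a cell when its dose, relative to the median cardiomyocyte, was at least 1.3 or at most 0.7. The dose was taken at 5000 UMIs per cell of the genes used for it. It is a measure of transcripts, added after the variance ratio was seen, that does not part whole chromosomes from segments. A gained or lost chromosome was found in 154 of 580 cardiomyocytes labelled knockout, 26.6% [23.0, 30.3], and in 9 of 491 labelled wildtype, 1.83% [0.842, 3.45]. Simulated cells with equal chromosomes gave 0.11% and 0.06%. Endothelial/endocardial cells labelled wildtype gave 5.80% against 0.14% in their simulated cells. The simulated share is therefore no rate of calls expected in real cells without gains or losses. Gained chromosomes had a median dose of 1.46 and lost ones of 0.561, 112 cells had a gain, 110 a loss, and 93 had at least 2 chromosomes out of balance, up to 11. Each of the 19 autosomes was both gained and lost, with chromosome 18 gained in 22 cells and chromosome 16 lost in 22. The share was 38.3% [32.2, 44.8] in ventricular cells labelled knockout and 11.8% [4.44, 23.9] in atrial ones. Other classes differed less: 5.80% [4.32, 7.59] and 7.58% [5.76, 9.75] in endothelial/endocardial cells, 2.76% (upper bound 5.36) and 7.12% (lower bound 4.57) in mesenchymal cells, and 2.88% [1.74, 4.47] and 5.61% [4.65, 6.70] in epicardial cells. Intervals of these pairs overlapped in the endothelial/endocardial and mesenchymal classes and lay apart in the epicardial class.

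**Figure D3:**
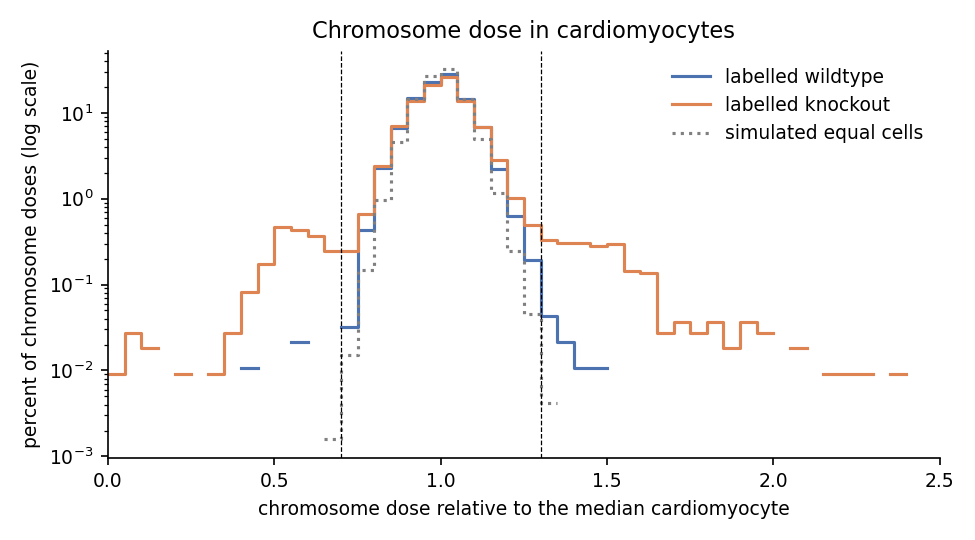
Share of chromosome doses (percent, log scale) by dose relative to the median cardiomyocyte, for the library labelled wildtype, the library labelled knockout and simulated equal cells. It covers 19 autosomes and all cardiomyocytes with at least 5000 UMIs of the genes used for the dose. Dashed lines mark doses of 0.7 and 1.3. The library labelled knockout has added doses outside both lines, with medians of 0.561 and 1.46.

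**Figure D4:**
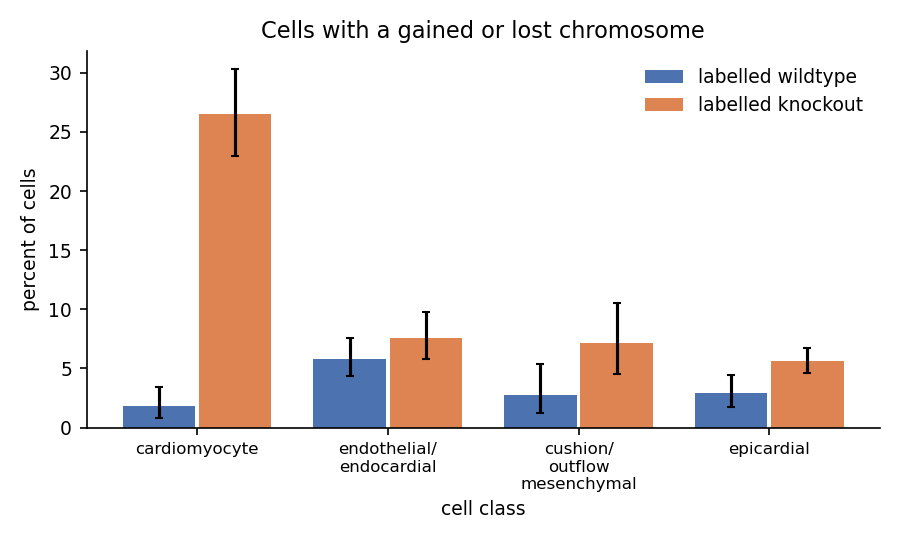
Percent of cells with at least 1 gained or lost chromosome, by cell class and library, with 95% Clopper-Pearson intervals for counting error. Cardiomyocytes labelled knockout stand at 26.6% and those labelled wildtype at 1.83%, and no other bar exceeds 7.58%.

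Endothelial/endocardial cells labelled knockout had more transcripts of division and fewer of the interferon response. The G2/M list rose, at 0.46 (percentile 100; 47 higher, 0 lower, 6 holding 0), with the cyclin Ccnb1 at 0.99 [0.82, 1.16] and Ube2c at 0.85 [0.76, 0.93], as did the S phase list at 0.50 (37 higher, 0 lower) and the spindle list at 0.43 (18 higher, 0 lower). Interferon genes fell, at -2.11 (17 of 17 lower), with Ifi44 at -3.61 [-5.28, -2.32], and p53 targets fell, at -0.32 (10 lower, 2 higher of 24), with the death receptor Fas at -1.89 and Cdkn1a at -0.80. Heat shock genes (0.68), Bmp targets (0.37), Notch and transition genes (0.32) and cardiac transcription factors (0.23) rose, with Sox9 at 3.47 [2.95, 4.03] and Gata5 at 1.21, and matrix (-0.24) and trabecular genes (-0.71) fell. The single genes at the ends were Hapln1 at 2.32 [2.25, 2.39], the neuregulin receptor Erbb4 at 2.25, Rian at 1.99, Mpped2 at 1.75 and Gpc3 at 1.67, and Fbln5 at -8.21 (677 and 2 UMIs), Fabp4 at -6.68 (463 to 4.53 CPM), elastin Eln at -4.57, Mgp at -3.91 and Tcf15 at -3.70. Fabp4 and Tcf15 set apart cluster 15, which held 188 cells labelled wildtype and 40 labelled knockout. Sarcomere genes fell at -0.41, but turned to 1.42 after free RNA was subtracted.

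Cushion/outflow mesenchymal cells, all of cluster 4, showed the same direction for division and p53 genes as the endothelial/endocardial cells. Clusters 0 and 5, left without a name, also carried mesenchymal markers and are not part of these values. S phase (0.78; 38 higher, 0 lower), spindle (0.60; 17 higher, 0 lower) and G2/M genes (0.44; 41 higher, 1 lower) rose, with Cdc6 at 1.65 and Birc5 at 1.04, both with intervals above 0. The p53 targets fell, at -0.52 (9 lower, 0 higher of 23), with Eda2r at -1.93, Trp53inp1 at -1.45 and Cdkn1a at -1.09. Glycolysis rose, at 0.64 (12 higher, 1 lower of 15), with hexokinase Hk2 at 1.54 [1.14, 1.95], and oxidative phosphorylation rose, at 0.36 (19 higher, 0 lower of 25). Matrix genes fell, at -0.61 (16 lower, 4 higher), with lumican Lum at -4.96 (624 to 20.1 CPM), as did Fgf and Erk targets (-0.55), interferon genes (-0.72), immediate early genes (-0.42), kinase inhibitors (-0.87), calcium handling (-1.62), sarcomere (-0.76) and trabecular genes (-1.15), the last turning to 0.46 after free RNA was subtracted. Heat shock genes rose, at 0.53. Ankrd1 at 2.69 [2.21, 3.20], Mt1 at 2.57, Nrg1 at 2.44, Nrxn3 at 2.36 and Akr1b8 at 2.35 were highest, and Sntg1 at -6.83, Chrm2 at -6.79 (209 and 2 UMIs), decorin Dcn at -6.10 (222 to 3.23 CPM), Dpt at -6.04 and Gabrb1 at -5.96 lowest.

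Epicardial cells, from cluster 6 in the library labelled wildtype and clusters 25 and 24 in the library labelled knockout, differed in division and interferon genes. The G2/M (1.07; 52 higher, 0 lower), spindle (1.04; 21 higher, 0 lower) and S phase lists (1.01; 42 higher, 0 lower) rose, with Ttk at 1.62 [1.33, 1.92] and Ccne2 at 2.01 [1.77, 2.26]. Interferon genes fell, at -2.46 (12 of 12 lower), with Isg15 at -5.38, and the p53 targets stayed inside the range, at 0.04 (percentile 76.8). Bmp targets (0.79), heat shock (0.58), compact myocardium (0.50) and Notch and transition genes (0.42) rose, and matrix (-0.38), sarcomere (-0.44), calcium handling (-0.86) and trabecular genes (-0.82) fell. Hapln1 at 4.91 [4.60, 5.24], the integrin Itga4 at 4.16, Asb4 at 3.59, Hsd11b2 at 3.46 and the cyclin Ccnd1 at 2.85 were highest, and Thbs2 at -7.69, Fmo2 at -6.44, Pcdh15 at -6.40, Igfbp6 at -6.40 and Il1rapl1 at -5.90 lowest. The cluster labelled wildtype lost its epicardial name at a Leiden resolution of 2.0, where 2 epicardial cells were left in that library, so no value could be given there.

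Erythroid cells, from clusters 8 and 3 in the library labelled wildtype and cluster 18 in the library labelled knockout, differed in their globins. Adult beta-globins Hbb-bt and Hbb-bs made up 21.3% [21.3, 21.3] of beta-globin UMIs in the library labelled wildtype and 4.33% [4.31, 4.34] in the library labelled knockout, and the embryonic Hbb-bh1 0.577% and 13.9%. After thinning, the adult shares were 22.3% and 4.46%. The embryonic alpha-globin Hba-x made up 25.2% and 71.9% of alpha-globin UMIs, and hemoglobin 83.7% and 48.1% of all erythroid UMIs. Relative to the median gene, S phase (2.16), spindle (1.71) and G2/M genes (1.66) rose, with Cenph at 3.34, Vars at 3.30, Hist1h4d at 3.26, metallothionein Mt1 at 3.25 and Kif15 at 3.18 highest, and Tspo2 at -9.30, heme oxygenase Hmox1 at -9.20, Tcp11l2 at -8.43, Neat1 at -7.02 and Fam174b at -6.44 lowest. The globins and Mt1 also set apart these clusters.

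**Figure D5:**
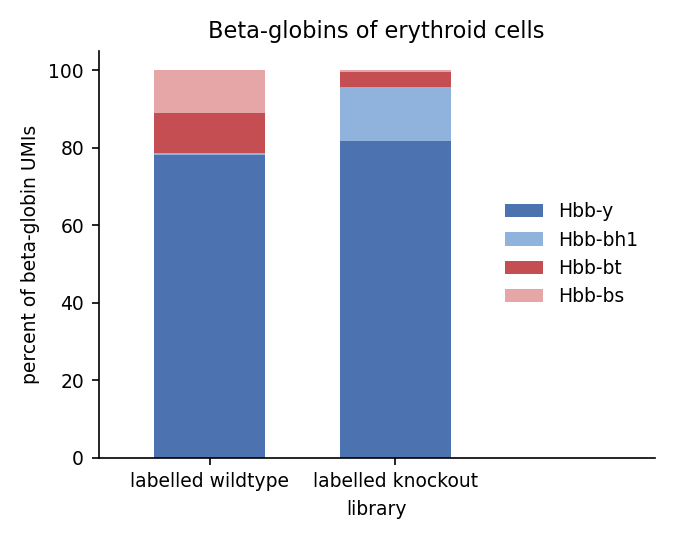
Percent of the beta-globin UMIs of erythroid cells from each beta-globin gene, in 1 stacked bar per library. Adult globins Hbb-bt and Hbb-bs reach 21.3% in the library labelled wildtype and 4.33% in the library labelled knockout, which instead has 13.9% of embryonic Hbb-bh1.

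Hmga2 was higher in all 5 classes labelled knockout on the plain log2 scale. It had log2 ratios of 2.90 [2.70, 3.12] in cardiomyocytes, 1.35 [1.25, 1.46] in endothelial/endocardial, 2.21 [2.10, 2.32] in mesenchymal and 2.23 [2.15, 2.31] in epicardial cells, and of 1.27 in erythroid cells, which turns to -0.88 relative to the median gene. Lin28b and Igf2bp1, chosen after their values were seen, stood at 0.63 and 0.85 in endothelial/endocardial cells. The pools also differed in sex: Uty, a gene of the Y chromosome, had 2635 UMIs in the library labelled wildtype and 0 in the library labelled knockout, Eif2s3y had 1875 and 1, and Xist, the RNA of the inactive X chromosome, stood at 225 and 528 CPM. Stage, sex, litter and library therefore cannot be told apart from genotype in any of these ratios.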

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

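The tests of label exchange, of another stage in the pool, of fewer mitotic cells, of reads outside the deleted part, of chromosome variance in ventricular cells and of both gene sets of a chromosome were chosen after the result was seen; leaving out the most abundant genes was set before the data were examined, but what it would show was written down afterwards; those of free RNA and of depth were written down before their results were seen.

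Several changes went in opposite directions in cardiomyocytes and in other classes, which is why they are listed here; with 1 library per genotype the difference between classes was not tested. On the plain log2 scale Bub1b stood at -0.88 in cardiomyocytes, 0.50 in endothelial/endocardial, 0.37 in mesenchymal and 0.88 in epicardial cells. In the same order the spindle checkpoint list without Bub1b stood at -0.11, 0.43, 0.60 and 1.04, the G2/M list at -0.18, 0.46, 0.44 and 1.07, and the extracellular matrix list at 1.21, -0.24, -0.61 and -0.38. The p53 targets stood at 0.30 in cardiomyocytes, -0.32 in endothelial/endocardial and -0.52 in mesenchymal cells. Between cardiomyocytes and mesenchymal cells, glycolysis went from -0.21 to 0.64, oxidative phosphorylation from -0.32 to 0.36, and Fgf and Erk targets from 0.70 to -0.55. In cardiomyocytes the interval of the spindle list holds 0 [-0.20, 0.13] and the list turned to 0.047 in thinned cells, and the matrix list turned to -0.027 after free RNA was subtracted, -0.12 in atrial cells and -0.16 at a mitochondrial limit of 10%.

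Chromosome shares varied more between cardiomyocytes labelled knockout. Without the 5 most abundant genes of each chromosome the ratio of variances was 1.45 [1.32, 1.92], which argues against a few abundant genes as the whole cause. In ventricular cells, outside the cell cycle and variable genes, it was 2.401 [2.06, 2.93]. The higher variance thus remained without the other subtypes and those genes. Ventricular cells are a range of a score, and large sub-clusters of cardiomyocytes came almost only from 1 library. One held 165 cells labelled wildtype and 0 labelled knockout, another 1 and 166. This subset therefore does not equalise cell states, and another mix of states or cycle phases stays open. Unequal chromosome sets between cells are a candidate explanation: genes at odd and at even places along a chromosome deviated together in the same cell, with an excess correlation of 0.480 [0.399, 0.564] labelled knockout and 0.0400 [-0.0324, 0.112] labelled wildtype, a difference of 0.440. Labelled knockout and wildtype, the excess was 0.0958 and 0.0767 in endothelial/endocardial, 0.153 [0.0553, 0.217] and 0.0782 in mesenchymal and 0.0912 [0.0639, 0.127] and 0.0185 in epicardial cells, with overlapping intervals in each class, so a smaller excess in the last 2 classes stays open. Genotype stays open as the reason, untested, since each genotype had 1 library.

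Cells labelled wildtype had a higher share of adult beta-globin and, on the plain log2 scale, less Hmga2. An exchange of both labels would put less Bub1b into cardiomyocytes labelled wildtype. The log2 ratio of -0.88 goes the other way, which counts against an exchange only if reads of the deleted allele are lost. Macrophages, taken as unmarked by the Cre, had a similar ratio of -0.84 [-1.30, -0.40], so this value is weak evidence on the labels. The lowest log2 ratio of Hmga2 over the 4 classes other than erythroid was 1.29 after free RNA was subtracted. Erythroid cells held only 1.91 CPM of Hmga2 labelled wildtype and 4.60 labelled knockout, so their free RNA brings little of it. That test could hardly have come out otherwise, and no conclusion on free RNA is drawn from it. Thinning could not test unequal depth: the adult beta-globin share differed 5.00-fold after it, but thinning keeps such a share on average. For the same reason, fewer UMIs per cell would not by themselves shift that share on average. Embryos of another stage in the pool labelled wildtype cannot be told apart from an effect of genotype, because the stage of single embryos is not given in the sources used here; the lowest log2 ratio of Hmga2, Lin28b and Igf2bp1 in endothelial/endocardial cells was 0.63.

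Bub1b was lower in cardiomyocytes labelled knockout, and otherwise only in macrophages among the classes compared for it. Fewer mitotic cells could lower the other checkpoint genes too, but their median log2 ratio was -0.11. Its lower bound of -0.20 lay above the upper bound of -0.68 for Bub1b. Members of that list need not all follow division as closely as Bub1b, and Mki67 fell further, to -0.64 [-0.75, -0.54]. That interval overlaps the interval of Bub1b, so fewer dividing cells stay open for a part of the drop or more. In the classes where Bub1b was higher it still stood below Bub1, at 0.88 against 1.37 in epicardial cells. A ratio below that of Bub1 was therefore not particular to cardiomyocytes and macrophages. Free RNA would bring at most 12.5% of the Bub1b UMIs left in these cells. Reads from the 3' end outside the deleted part cannot be told apart from cells that kept Bub1b, since the part deleted is not given in the sources used here and 0.545 of the level labelled wildtype was left. Loss of the gene in these cells stays open, untested.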

How the results depend on the processing

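The alternatives without a gene minimum, with at least 10 or 20 UMIs of a list, without mixed sub-clusters, in atrial cells, in ventricular cells for chromosome measures, and with doses of 1.4 and 0.6 were chosen after the result was seen; the others were set before the data were examined. No paired analysis was possible because each genotype had 1 library, and values were held against their counting interval, or for lists against the order-statistic interval; all ratios here are on the plain log2 scale. Where a value moved, the cause was not tested, except that a changed minimum of UMIs or genes, or a changed mitochondrial limit, by its construction changes which cells are kept.

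Bub1b in cardiomyocytes kept its direction under every alternative run, from -0.73 in thinned cells to -1.09 without mixed sub-clusters, the only value outside its interval. The p53 targets and the sarcomere list of cardiomyocytes stayed inside their intervals under every alternative run.

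With at least 1000 UMIs per cell, 8152 cells labelled wildtype and 6557 labelled knockout were kept, and cardiomyocytes made up 15.3% and 17.5% of non-blood cells. With at least 5000 UMIs, 6221 cells labelled wildtype were kept, 12.9% of the non-blood cells being cardiomyocytes. A mitochondrial limit of 10% kept 6659 and 5136 cells, with 8.37% and 10.4% cardiomyocytes, 96.9% of those labelled wildtype with G2/M UMIs, and turned the matrix list of cardiomyocytes to -0.16. Without doublet removal 7489 and 5692 cells were kept, with 15.5% cardiomyocytes labelled knockout. Without a gene minimum 10193 cells labelled wildtype were kept, with 10.1% cardiomyocytes. Naming cells by highest marker score gave 12.4% labelled wildtype and 12.2% labelled knockout, so the direction between the libraries turned.

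The G2/M share of cardiomyocytes labelled wildtype and knockout was 98.8% and 98.8% at 2 UMIs, 86.1% and 89.6% at 5, 64.3% and 65.6% at 10, 43.4% and 47.1% at 20, and 99.2% and 99.8% in unthinned cells. The share with a gained or lost chromosome was 0.815% and 20.5% at doses of 1.4 and 0.6, and 38.3% labelled knockout in ventricular cells, where the variance ratio was 2.26.

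In ventricular cells the calcium list of cardiomyocytes turned to 0.046 and the trabecular list to 0.79, and the G2/M list stood at -0.27. In atrial cells the G2/M list turned to 0.14, the spindle list to 0.050, glycolysis to 0.30, hypoxia to 0.21, oxidative phosphorylation to 0.012 and the matrix list to -0.12. Thinning turned the spindle list to 0.047. Subtracting free RNA turned the matrix list of cardiomyocytes to -0.027, the sarcomere list of endothelial/endocardial cells to 1.42 and the trabecular list of mesenchymal cells to 0.46, and put the G2/M list of cardiomyocytes at -0.29, as did median-of-ratios scaling (-0.29). Without mixed sub-clusters it stood at -0.30, and Fbln2 turned to -0.36.

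Over all alternatives, 2119 of 2460 values of named genes lay inside their interval, 128 outside and higher, 212 outside and lower and 1 turned. For lists these were 1337 of 1385 inside, 13 higher, 22 lower and 13 turned, for cycling shares 149 of 252 inside, 40 higher and 63 lower, and for class shares 50 of 90 inside, 20 higher and 20 lower.

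Without a mitochondrial limit, without doublet removal and at a Leiden resolution of 2.0, only 63, 67 and 2 cells labelled wildtype were named epicardial, against 921, so the epicardial ratios and cycling shares have no value there. Subtracting free RNA left genes at 0 in a library, among them Has2, Hapln1, Sox9, Fbln2, Unc5c, Cdh11, Id1, Id3 and Twist1 in cardiomyocytes, Erbb4 and Gpc3 in endothelial/endocardial and Ankrd1 and Dcn in mesenchymal cells, and the hemoglobin lists and the sarcomere list of mesenchymal cells without a value; thinning did so for Eda2r in cardiomyocytes, Chrm2 in mesenchymal and Ifit3 in endothelial/endocardial cells. Depth limits the Bub1b share of single cells and the dose measure, which left out 111 cardiomyocytes labelled wildtype and 16 labelled knockout with too few UMIs.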

Other observations

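Both tests with a prediction below were chosen before their result was seen; the added comparisons, of Cdkn1a, Bub1, Mki67, ventricular cells and chromosomes other than 2, were not part of those predictions.

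The 2 sets of genes of a chromosome gave doses close to each other in cardiomyocytes labelled knockout. Where the first set of a chromosome had a gain, at a median dose of 1.41, the second set, not used to choose it, stood at 1.33 (upper bound 1.39), and where the first set had a loss, at 0.569, the second stood at 0.6001 [0.578, 0.631]. In cardiomyocytes labelled wildtype the second set stood at 1.01 and 0.972. The share of cells labelled knockout with such a chromosome was 18.9% in outflow tract, 21.5% in atrioventricular canal and 17.2% in sinoatrial cells. In epicardial cells with a loss in the first set, the second stood at 0.883 [0.777, 0.916] labelled knockout and 0.997 [0.967, 1.02] labelled wildtype. With a gain, their intervals overlapped, at 1.03 [1.01, 1.06] and 1 [0.970, 1.03]. In endothelial/endocardial and mesenchymal cells the intervals of both libraries overlapped for gains and losses.

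Smaller populations also differed. Macrophages numbered 254 labelled wildtype (3.61%) and 51 labelled knockout (0.939%), and megakaryocytes 44 (0.625%) and 90 (1.66%). Cluster 27, left without a name, held 54 cells, all labelled knockout, set apart by the hypoxia genes Ndrg1, P4ha2, Vegfa, Ankrd37 and Adm, and cluster 22, with 9 and 117 cells, was set apart by Myb, Ikzf1 and Mpo, genes of blood progenitors. Clusters 0, 1 and 5, also without a name, held 334, 268 and 872 cells labelled wildtype and 0, 0 and 5 labelled knockout. Of the mesenchymal markers, 8 of 11 were raised in cluster 0 and 6 of 11 in cluster 5. The top 10 genes of both clusters held no such marker. The mesenchymal class, with 480 cells labelled wildtype, leaves these clusters out.

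The p53 targets may rise in cells whose chromosomes are out of balance. In the tertile of cardiomyocytes labelled knockout with the most unequal chromosome shares they made up 922 CPM [893, 952], against 645 [621, 671] in the most equal tertile, a log2 ratio of 0.51 [0.44, 0.59]; labelled wildtype it was -0.04 [-0.13, 0.05]. Cells labelled knockout with a gained or lost chromosome had Cdkn1a at 105 CPM, against 25.8 in cells without, a log2 ratio of 2.03 [1.78, 2.27], and in ventricular cells 2.48. Labelled wildtype, where 9 cells had such a chromosome, this split gave 0.71 [-1.59, 2.29] for Cdkn1a. For the p53 targets it gave 0.21 [-0.12, 0.52] labelled wildtype and 0.67 [0.60, 0.73] labelled knockout. Both wildtype values point the same way, with intervals that hold 0. The order of events was not tested.

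Cardiomyocytes labelled knockout that still hold Bub1b transcripts may be those without a chromosome gain or loss. Bub1b stood at 18.7 CPM in cells with a gained or lost chromosome and 36.1 in cells without, a log2 ratio of -0.95 [-1.37, -0.55], and at -0.87 [-1.31, -0.45] when cells with an altered chromosome 2, which carries the gene, were left out. Slower division would lower other mitotic genes too: Bub1 stood at -0.13 [-0.42, 0.16] and Mki67 at -0.23 [-0.42, -0.05], and in ventricular cells Bub1 at -0.39 [-0.79, -0.01] beside Bub1b at -0.95, so a part of the drop stays open. Between the most unequal and the most equal tertile the ratio of Bub1b was -0.28 [-0.66, 0.10], an interval that holds 0, and that of Bub1 was -0.35 [-0.65, -0.04], so this split shows no drop particular to Bub1b. In the 9 cells labelled wildtype with a gained or lost chromosome Bub1b was also lower, at -1.73 [-4.77, 0.14].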
